A study of Homo sapiens with 18 samples.

How the data were processed

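RNA was measured in 18 libraries of PMA-treated THP-1 cells, 6 in each of 3 groups: uninfected, infected with Candida albicans for 2 h, and infected in the presence of 62.5 µg/mL of cinnamaldehyde for 2 h. Per the labels, libraries were made from polyA RNA with a stranded mRNA kit and sequenced as read pairs. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM and the GRCh38 build, without versions or the role of each, and the annotation release is not given in the sources used here. The vehicle of cinnamaldehyde is not stated in the labels. The authors deposited a table of expected counts per gene and library, that is, estimated counts that need not be whole where a read matches several transcripts or genes. The authors also deposited a table of TPM values (scaled for transcript length and library total) for the same genes and libraries. Of the expected counts 90.02% were whole numbers, and 68.9% of those above 0. Each table held 78945 lines after its header, of which 13 held overflow annotation text with no gene and no value and were left out. The 78932 genes that remained included 42745 with a name and 19554 of the protein-coding class. That class was taken from the files, which put some well-known protein-coding genes, such as H2AC6, ANGPTL4 and CEBPG, in another class. Positions came from GENCODE release 29 on GRCh38 for the 57356 gene IDs found there.

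Groups and library numbers were taken from the labels. The labels do not say that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All 18 libraries were counted as separate, since counts of any pair within a group differed by more than sampling noise: the chi-square per gene between libraries of a group was at least 2.196. The design had been fixed for whole-number counts. Because the deposited values were expected counts, they were rounded to whole numbers before the count tests. Genes were kept by edgeR's filterByExpr, which left 16189 genes (12718 protein-coding) holding at least 99.85% of each library's counts. Library totals of 17994193 to 23725843 were scaled by the TMM method. All 18 libraries entered a single edgeR 4.0.16 quasi-likelihood fit in R 4.3.3, with a common biological coefficient of variation of 8.95%. The comparisons were infected against uninfected, infected with against without cinnamaldehyde, and infected with cinnamaldehyde against uninfected. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Levels are CPM with SDs over 6 libraries. For genes with fewer than 10 counts in a group, the ratio is given with a 95% interval from the counts, which covers counting error only.

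A total of 790 entries in 42 gene lists were fixed before the data were examined, on inflammation, fungal recognition, stress responses, metabolism, cell fate, other cell types and RNA quality. All 790 matched a gene of the files, and the 39 lists with at least 3 tested members were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01. Adjustment ran over all lists and the 3 comparisons together. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. The B cell, erythroid and platelet, and epithelial lists had fewer than 3 tested members. Lists described at length were chosen after their results had been seen. Library measures (total, genes with at least 10 counts, and shares of the 10 most abundant, mitochondrial and ribosomal protein genes) were compared by two-sided exact permutation tests over the 924 splits of 6 against 6 libraries, adjusted over 15 tests. Principal components used log2 CPM of the 1000 most variable genes.

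Genes named in the text followed a rule fixed before the data were examined. It took the 6 highest and 6 lowest log2 fold changes per main comparison (4 and 4 in the third). These came from named protein-coding genes past the threshold, with at least 5 CPM in the higher group and no overlap of the groups' libraries. It added the 3 members of smallest p and the largest change against the direction from each list described at length, and 21 genes of inflammation, stress and reference in the main comparisons. Genes named outside this rule were chosen after their values had been seen.

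The code was tested on simulated counts with 200 changed genes for each comparison, besides a list of further genes changed 1.5-fold. Simulated libraries of a group shared the same mean for each gene. Uneven libraries, as seen in the infected group, were thus not simulated. For infection it recovered 73.1%, 88.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 6.64% of calls false. For cinnamaldehyde it recovered 65.7%, 91% and 100%, with 3.92% false, and for the third comparison 76.1%, 92.5% and 98.5%, with 6.13% false. Alternatives fixed before the data were examined were DESeq2-type size factors, library totals, other filters, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the library number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), protein-coding genes only, a test against a 1.5-fold change, and leaving out each library. Comparisons within libraries 1 to 3 and 4 to 6, and with each choice of 3 infected libraries, were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.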

Results

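The transcriptomes of THP-1 cells, a human monocytic leukaemia line, were measured after phorbol ester treatment had turned the cells into adherent macrophage-like cells. Cells at 800000 per mL received 100 ng/mL of phorbol 12-myristate 13-acetate (PMA) for 24 h. The cultures then fell into 3 groups of 6 libraries each. The first group was left uninfected. The second, called infected, was incubated for 2 h with the yeast Candida albicans, strain SC5314, at 2400000 colony-forming units per mL. The third was incubated for the same 2 h with the yeast and 62.5 µg/mL of cinnamaldehyde, the main aldehyde of cinnamon oil. No group received cinnamaldehyde without the yeast, so an effect of the compound on the host cells and an effect through the yeast are not separated by the design. PolyA RNA was sequenced. The deposited table gave expected counts for 78932 genes, of which 16189 passed the filter on low counts and were tested. Total counts per library ranged from 17994193 to 23725843, and group means did not differ in total (exact permutation adjusted p of 0.354 or more for all 3 pairs of groups). Levels are given in CPM, each gene's count scaled to the library total, as mean ± SD over n = 6 libraries. Fold changes and adjusted p-values come from edgeR's quasi-likelihood test.

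The cinnamaldehyde-treated libraries stood apart from all others. On the first principal component, which held 60.2% of the variance of the 1000 most variable genes, they lay between 35.17 and 39.2, and the other 12 libraries lay between -21.05 and -15.77. The second component held 5.85% and spread the infected group. Infected libraries 1, 2 and 3 lay at 12.91 to 19.64. Infected libraries 4, 5 and 6 at -6.41 to 1.14, overlapping the uninfected libraries (-11.92 to 0.286). Because the labels number the libraries 1 to 6 in each group and name no batch, each comparison is also given within libraries 1 to 3 and within libraries 4 to 6, a division chosen after the values had been seen. Mitochondrially encoded transcripts made up 2.71 ± 0.077% of counts in uninfected, 2.39 ± 0.312% in infected and 1.47 ± 0.080% in cinnamaldehyde-treated libraries. The fall with cinnamaldehyde was past the threshold (exact permutation p = 0.00217, the smallest that 6 against 6 libraries can give, adjusted p = 0.0065). The difference between infected and uninfected libraries was not past it after adjustment over 15 tests (exact permutation p = 0.0325, adjusted p = 0.0541). Ribosomal protein transcripts took 3.65 ± 0.0813%, 3.42 ± 0.353% and 4.34 ± 0.298% of counts in the same order (exact permutation adjusted p = 0.221 for infection and 0.0065 for cinnamaldehyde). The 10 most abundant genes took 7.63 ± 0.0838%, 7.68 ± 0.0712% and 7.83 ± 0.114% (exact permutation adjusted p = 0.319 for infection and 0.0541 for cinnamaldehyde). In shares of TPM the direction turned, with 11.2 ± 0.207%, 11.1 ± 0.308% and 9.88 ± 0.105% (exact permutation p = 0.595 for infection and 0.00217 for cinnamaldehyde, not adjusted). The number of genes with at least 10 counts was 15880 ± 179 in uninfected, 15860 ± 123 in infected and 15480 ± 326 in cinnamaldehyde-treated libraries (exact permutation adjusted p = 0.949 for infection and 0.0065 for cinnamaldehyde). Counted from 1 count upward, the number was 25280 ± 287 in infected and 24860 ± 684 in treated libraries and did not pass (exact permutation p = 0.227, not adjusted).

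**Figure D1:**
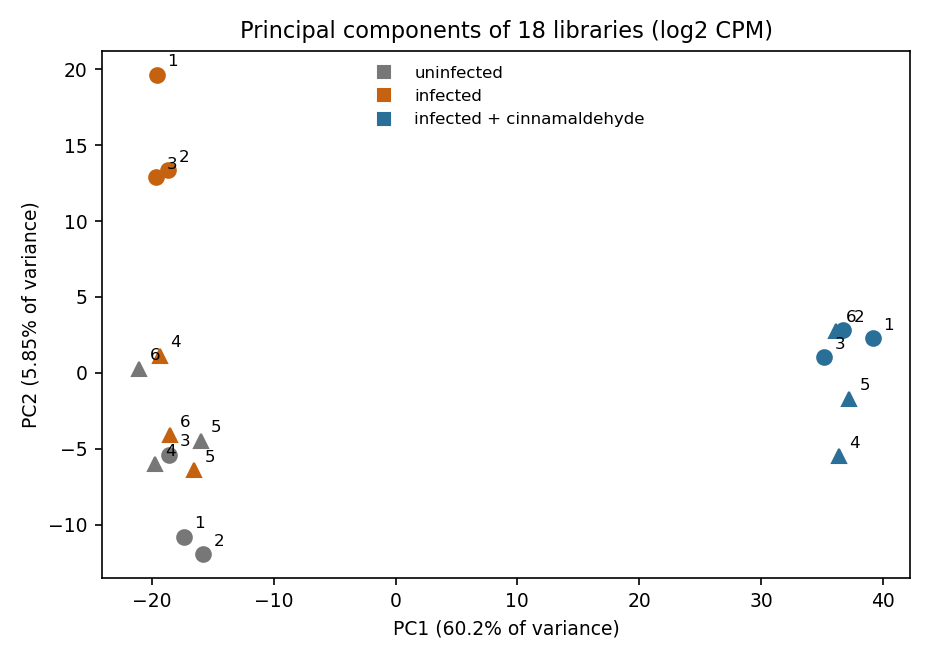
Principal components of log2 CPM of the 18 libraries, with the first component (60.2% of variance) on the x axis and the second (5.85%) on the y axis. Each point is a library with its number (circles for 1 to 3, triangles for 4 to 6), grey for uninfected, orange for infected and blue for infected with cinnamaldehyde, and the blue points lie at 35.17 to 39.2 on the x axis.

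The first comparison, infected against uninfected cells, asked which macrophage transcripts changed within 2 h of contact with the yeast. Of the immediate-early genes 17 of 29 rose, of the NF-kB targets 6 of 18, of the integrated stress response targets 8 of 23 and of other hypoxia targets 8 of 16. The last of these lists did not pass with an estimated correlation (adjusted p = 0.12). DDIT4, a stress-induced inhibitor of mTORC1 signalling, rose from 29.3 ± 3.80 to 137 ± 94.8 CPM, a 4.67-fold change (log2 fold change 2.22, SE 0.34, adjusted p = 0.000448). ADM, which encodes the vasodilator peptide adrenomedullin, rose from 9.31 ± 1.19 to 36.6 ± 22.3 CPM, or 3.92-fold (adjusted p = 0.000377). The chemokine receptor gene CXCR4 rose 2.68-fold, from 19.3 ± 2.47 to 52.0 ± 19.8 CPM (adjusted p = 6.85e-05). Among the falls, SLC30A1, which encodes a zinc exporter, went from 41.9 ± 2.42 to 24.1 ± 5.78 CPM (log2 fold change -0.79, SE 0.11, adjusted p = 0.000172). Levels of TNF and CXCL8, the genes of the cytokines TNF and interleukin-8, were 21.4 ± 2.17 against 21.6 ± 2.12 CPM and 1496 ± 298 against 1475 ± 115 CPM (log2 fold changes of -0.02, SE 0.089, and 0.02, SE 0.12, adjusted p = 0.927 and 0.93). For CXCL8 the log2 fold change was -0.24 in libraries 1 to 3 and 0.24 in 4 to 6 (adjusted p = 0.101 and 0.761), and these differed from each other (adjusted p = 0.0307). For TNF they were -0.06 and 0.03 (adjusted p = 0.643 and 0.994).

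Of 29 immediate-early genes, which are transcribed within minutes of a stimulus, 17 rose and 1 fell (18 and 1 when adjusted over the list alone). The rise of the list was past the threshold of the camera gene set test (adjusted p = 3.16e-24, and adjusted p = 0.0276 with an estimated correlation). The nuclear receptor genes NR4A2 (from 0.592 ± 0.248 to 3.59 ± 1.43 CPM, 5.97-fold, adjusted p = 1.71e-05) and NR4A3 (1.93-fold, adjusted p = 1.71e-05) and the transcription factor genes FOSB (2.48-fold, adjusted p = 4.92e-05) and MAFF (1.76-fold, adjusted p = 8.25e-06) rose. EGR1 rose 1.31-fold (adjusted p = 0.021) and ATF3 1.32-fold (adjusted p = 0.0176). MYC fell from 123 ± 3.24 to 101 ± 8.45 CPM (log2 fold change -0.28, adjusted p = 0.00417), and FOS did not pass (93.5 ± 11.3 against 85.8 ± 2.84 CPM, adjusted p = 0.355). Of 18 NF-kB feedback and survival targets, 6 rose and none fell (8 and 0 when adjusted over the list alone, camera adjusted p = 3.29e-08, and adjusted p = 0.0481 with an estimated correlation). They included IER3 (1.54-fold, adjusted p = 0.000104), TNFAIP3 (1.35-fold, adjusted p = 0.000662), whose product restrains NF-kB signalling, and NFKB2 (1.29-fold, adjusted p = 0.00526). Of 23 integrated stress response targets, 8 rose and CEBPG fell (10 and 1 when adjusted over the list alone, camera adjusted p = 1.53e-06, and adjusted p = 0.0316 with an estimated correlation). Besides DDIT4, CEBPB rose 1.92-fold (adjusted p = 0.00035) and PPP1R15A 1.24-fold (adjusted p = 0.00245), and DDIT3 rose 1.17-fold (adjusted p = 0.0383).

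Of 12 cytokine genes tested, 6 rose and none fell, the same counts when adjusted over the list alone (camera adjusted p = 0.000189, but adjusted p = 0.12 with an estimated correlation). IL1B rose from 1243 ± 46.3 to 1520 ± 53.6 CPM (1.22-fold, adjusted p = 0.000648), LIF 1.57-fold (adjusted p = 0.00153) and TNFSF15 1.23-fold (adjusted p = 0.00919). NLRP3, the gene of an inflammasome sensor, rose 1.4-fold (adjusted p = 0.00103). No chemokine gene of 16 passed the edgeR test (1 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.93). Of 25 interferon-stimulated genes, IFIT1, IFIT2 and XAF1 fell (the same count when adjusted over the list alone, log2 fold changes of -0.36, -0.34 and -0.26, camera adjusted p = 4e-04, but adjusted p = 0.549 with an estimated correlation). TLR2, which encodes a receptor for fungal cell wall components, gave 140 ± 17.8 against 150 ± 6.18 CPM (adjusted p = 0.412). It was lower in libraries 1 to 3 (log2 fold change -0.25, adjusted p = 0.00236) and not called in 4 to 6 (0.05, adjusted p = 0.983), and the divisions differed (adjusted p = 0.0131).

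Of 16 other HIF targets, 8 rose and none fell, also when adjusted over the list alone (camera adjusted p = 2.99e-08, but adjusted p = 0.12 with an estimated correlation), among them ADM, BHLHE40 (1.9-fold, adjusted p = 0.00153) and BNIP3L (1.31-fold, adjusted p = 0.00142). Of 22 glycolysis genes, 5 rose and none fell over all genes tested, and 17 rose when adjusted over the list alone (camera adjusted p = 4.73e-10, but adjusted p = 0.416 with an estimated correlation). These 5 were the glucose transporter genes SLC2A1 (from 306 ± 16.3 to 526 ± 184 CPM, 1.71-fold, adjusted p = 0.00408) and SLC2A3 (1.62-fold, adjusted p = 0.001), the hexokinase gene HK2 (1.4-fold, adjusted p = 0.00452), PDK1 and ALDOA. Of 14 LXR and PPAR lipid-handling genes, MYLIP, SREBF1, FASN and PLIN2 rose (4 rose and 1 fell when adjusted over the list alone, camera adjusted p = 0.039, but adjusted p = 0.542 with an estimated correlation). Of 22 proliferation genes, MCM2 and MCM5, which encode subunits of the replicative helicase, rose (4 when adjusted over the list alone, camera adjusted p = 0.016, but adjusted p = 0.326 with an estimated correlation).

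In 4 lists shifted downward by camera few or no members passed on their own. No member passed among 13 mitochondrially encoded genes (9 fell when adjusted over the list alone, median log2 fold change -0.17, camera adjusted p = 3.42e-05, but adjusted p = 0.542 with an estimated correlation). None passed among 48 ribosomal protein genes (none over the list alone, median -0.095, camera adjusted p = 0.000744, but adjusted p = 0.835 with an estimated correlation). None passed among 34 nuclear-encoded oxidative phosphorylation genes (none over the list alone, median -0.088, camera adjusted p = 0.00634, but adjusted p = 0.788 with an estimated correlation). Of 7 metallothionein and zinc response genes SLC30A1 alone fell (3 when adjusted over the list alone, camera adjusted p = 0.000389, but adjusted p = 0.193 with an estimated correlation). Of 9 replication-dependent histone genes, a list fixed as a sign of RNA quality, H2BC8, H2AC6 and H2BC21 fell (5 when adjusted over the list alone, camera adjusted p = 0.00016, but adjusted p = 0.12 with an estimated correlation). The other 25 lists did not pass, the lists of T and NK cell and of fibroblast markers among them (camera adjusted p = 0.718 for both). Members named here because a count was 5 or fewer, where the rule for named genes did not give them, were chosen after their values had been seen.

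PNRC1 (from 32.5 ± 1.44 to 83.0 ± 28.7 CPM, 2.55-fold, adjusted p = 1.77e-05) and PIK3R2 (2.33-fold, adjusted p = 0.0214) rose too. The homeobox gene DLX3 fell (from 11.4 ± 1.21 to 5.85 ± 0.943 CPM, adjusted p = 1.35e-05), as did the cytokine receptor gene IL21R (5.28 ± 0.682 to 2.66 ± 0.300 CPM, adjusted p = 4.92e-05). ID2 (log2 fold change -0.61, adjusted p = 0.000116), ZNF816 (log2 fold change -0.60, adjusted p = 0.00241) and CHAC2 (log2 fold change -0.59, adjusted p = 0.00749) fell as well. Over the genome, 544 genes were higher and 228 lower in infected cells (772, or 4.77% of those tested), of which 21 and 12 changed at least 2-fold. Over all 16189 genes tested, the infected and uninfected libraries did not overlap in 311 (1.92%), against the 0.216% that chance gives.

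**Figure D2:**
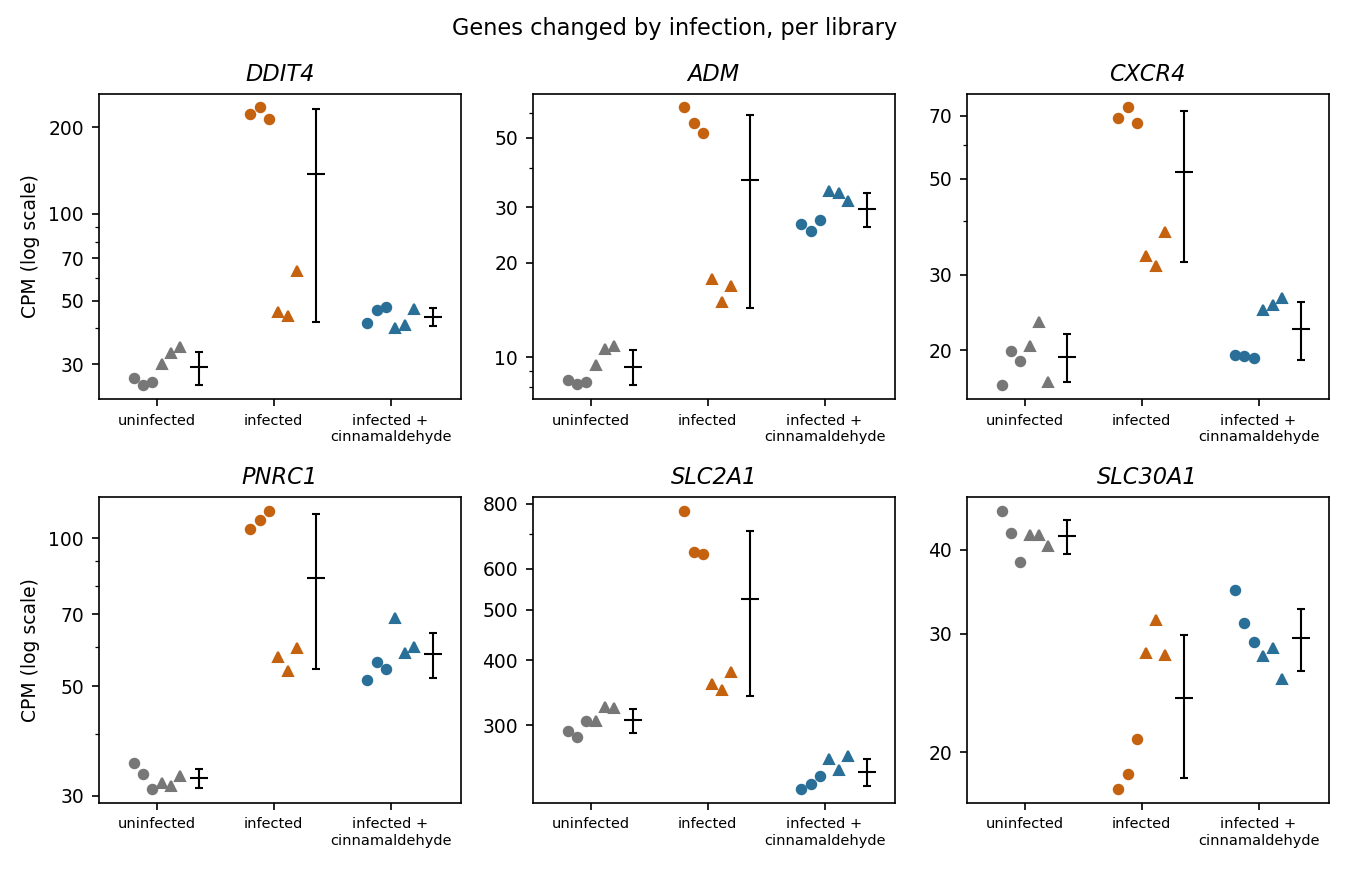
CPM on a log axis of 6 genes that changed with infection, by group on the x axis. Each point is a library (circles for libraries 1 to 3, triangles for 4 to 6) and the black bar is the mean ± SD over 6 libraries, and for DDIT4 the infected circles lie at 214 to 234 CPM and the infected triangles at 44.2 to 63.1 CPM.

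Within libraries 1 to 3, 6710 genes were called between infected and uninfected cells (3247 higher and 3463 lower, 229 of them at least 2-fold), and within libraries 4 to 6, 68 were called (49 and 19, 5 at least 2-fold). A test of the difference between these divisions called 4711 genes, and the log2 fold changes had a correlation of 0.0298 across genes, which are not independent replicates. The 55 genes called in both divisions went the same way. The log2 fold change of DDIT4 was 3.09 in libraries 1 to 3 and 0.65 in 4 to 6 (adjusted p = 4.86e-16 and 0.00102), that of ADM 2.77 and 0.68 (adjusted p = 2.74e-16 and 0.000121), that of SLC2A1 1.22 and 0.19 (adjusted p = 2.83e-12 and 0.322) and that of CEBPB 1.40 and 0.40 (adjusted p = 1.28e-09 and 0.0978). Those of NR4A2 (2.66 and 2.43, adjusted p = 4.9e-09 and 5.77e-06), DLX3 (-1.04 and -0.91, adjusted p = 1.38e-06 and 0.000115) and IL21R (-0.97 and -1.01, adjusted p = 0.000153 and 0.00241) lay closer together. Among the 36 named genes called with infection, the size of the change differed between the divisions for 24. Those included CXCR4 (1.916 and 0.752, difference adjusted p = 9.02e-06) and SLC30A1 (-1.145 and -0.512, difference adjusted p = 0.000561). All 36 were called in libraries 1 to 3 and 16 in 4 to 6. The other 20 were not called there (adjusted p of 0.0717 to 0.983). For 13 of these 20 the divisions differed (adjusted p of 1.46e-07 to 0.0318): NLRP3 (0.71 in libraries 1 to 3 and 0.23 in 4 to 6), EGR1 (0.62 and 0.11), NFKB2 (0.62 and 0.11), HK2 (0.76 and 0.15), LIF (0.95 and 0.30), HSPA1A (0.71 and 0.20), TNFAIP3 (0.59 and 0.27), BNIP3L (0.55 and 0.22), PPP1R15A (0.45 and 0.17), ACTB (0.31 and 0.033), CEBPG (-0.38 and -0.095), SLC2A1 and CEBPB. For MYC, DDIT3, CHAC2, ZNF816, PIK3R2, TNFSF15 and IL1B the difference did not pass (adjusted p of 0.151 to 0.858). Of the lists, the immediate-early, NF-kB, integrated stress response, HIF, cytokine, interferon-stimulated and metallothionein lists were called in both divisions. Few of their members passed on their own in libraries 4 to 6, where 8 immediate-early, 1 NF-kB, 1 integrated stress response and 2 HIF genes rose and 1 metallothionein list gene fell. No cytokine gene rose there and no interferon-stimulated gene fell (medians 0.0617 and -0.0595), against 7 and 13 in libraries 1 to 3. Those of mitochondrially encoded (12 of 13 fell), ribosomal protein (36 of 48 fell), oxidative phosphorylation (20 of 34 fell and 3 rose) and glycolysis genes (20 of 22 rose) passed camera in libraries 1 to 3 and not in 4 to 6, where ribosomal protein genes lay in the upward direction (camera adjusted p = 0.0664) and glycolysis gave an adjusted p of 0.0664 as well. So did the lists of proteasome genes (14 fell and 1 rose, camera adjusted p = 0.00746) and of phagocyte NADPH oxidase genes (4 rose and 1 fell, camera adjusted p = 0.0473). The lists of proliferation, histone, heat shock, apoptosis and eicosanoid genes passed in libraries 4 to 6 and not in 1 to 3 (camera adjusted p = 9.96e-05, 0.000404, 0.002, 0.0281 and 0.0485). With an estimated correlation, the immediate-early, NF-kB, cytokine and HIF lists held in both divisions, and the integrated stress response and glycolysis lists in 1 to 3. The other 7 calls in 1 to 3 and 8 in 4 to 6 were lost (adjusted p of 0.228 to 0.767 and of 0.0631 to 0.583 with an estimated correlation). Whether a list differed between the divisions was not tested.

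The number of infection calls depended on single libraries. The 772 calls became 217, 225, 251, 279 and 1306 without uninfected library 1, 2, 3, 4 or 6, and 284, 206, 197, 2676 and 1744 without infected library 1, 2, 3, 5 or 6. The 33 calls of at least 2-fold became 18 without uninfected library 2 and 18, 20, 19 and 57 without infected library 1, 2, 3 or 5. With library totals in place of TMM scaling, 601 genes were called and 47.4% of them were higher, against 70.5% in the main test. Some calls near the threshold were lost with another method. With limma-voom these were CEBPG, ACTB and HSPA1A (adjusted p of 0.0515 to 0.0591). On log2(TPM + 1) values they were MYC, CEBPG, ACTB, EGR1, ATF3, HSPA1A, ZNF816, TNFSF15, HK2 and NFKB2 (0.051 to 0.246). DDIT3 was lost with library totals (0.0626). Others were lost in the edgeR test when a library was left out. EGR1 was lost without uninfected library 1 or 2 or infected 2 or 3 (adjusted p of 0.0512 to 0.0687), ATF3 without infected 2 or 3 (0.0509 and 0.0569) and PIK3R2 without uninfected 1 or 2 or infected 1 (0.0512 to 0.0641). DDIT3 was lost without uninfected 1, 2 or 3 or infected 2, 3 or 4 (0.0521 to 0.108) and CEBPG without uninfected 1 to 5 or infected 1 to 4 (0.0521 to 0.123). HSPA1A, which rose 1.38-fold (adjusted p = 0.0263), was lost without uninfected 1, 2 or 4 or infected 1, 2 or 3 (0.0555 to 0.0785). ACTB, often used as a reference gene, rose 1.13-fold (adjusted p = 0.048), and its call was lost without uninfected 1 to 5 or infected 1, 2 or 3 (0.0502 to 0.119) and with library totals (adjusted p = 0.068). GAPDH did not pass (1449 ± 119 against 1322 ± 57.1 CPM, adjusted p = 0.146). TXNIP did not pass either (235 ± 41.8 against 286 ± 5.17 CPM, adjusted p = 0.0557), except without infected library 4, 5 or 6 (0.0378, 0.0091 and 0.0268) and with DESeq2 (0.0257). HMOX1, NQO1, TXNRD1 and DNAJB1 did not pass (adjusted p = 0.169, 0.38, 0.565 and 0.362). Several of these genes were called within libraries 1 to 3. There HMOX1 (log2 fold change 0.32, adjusted p = 0.000185), GAPDH (0.25, adjusted p = 0.00256) and FOS (0.22, adjusted p = 0.00467) were higher. TXNIP (-0.53, adjusted p = 2.39e-07), NQO1 (-0.22, adjusted p = 0.00891) and TXNRD1 (-0.13, adjusted p = 0.0479) were lower. None of the 6 was called in libraries 4 to 6 (adjusted p of 0.928 or more). The divisions differed for HMOX1, GAPDH, TXNIP and NQO1 (adjusted p = 0.00342, 0.0469, 0.000304 and 0.0282), and the difference did not pass for FOS and TXNRD1 (0.0693 and 0.0867). DNAJB1 was called in neither division (0.103 and 0.956).

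The second comparison, infected cells with against without cinnamaldehyde, asked how the compound altered the transcriptome of infected macrophages. All 24 heat shock (HSF1) target genes tested rose, also when adjusted over the list alone (median log2 fold change 1.63, camera adjusted p = 1.11e-108, and adjusted p = 0.00015 with an estimated correlation). HSPA6, which encodes a stress-inducible HSP70 chaperone, rose from 1.38 ± 0.446 to 2837 ± 578 CPM (2050-fold, log2 SE 0.18, adjusted p = 3.15e-22). HSPA1B rose from 71.4 ± 17.1 to 6121 ± 859 CPM (adjusted p = 9.84e-20) and HSPA1A from 31.7 ± 6.44 to 1470 ± 211 CPM (adjusted p = 7.33e-20). These neighbouring genes are near-identical copies, so the division of reads between them is uncertain. DNAJB1, an HSP40 co-chaperone gene, rose 18.6-fold to 2444 ± 356 CPM (adjusted p = 9.13e-21). A set of 7 chaperone genes took 0.770 ± 0.0249% of counts in infected and 2.61 ± 0.256% in cinnamaldehyde-treated libraries (exact permutation p = 0.00217, the smallest possible, tested after the values had been seen). For CRYAB, the gene of the small heat shock protein alphaB-crystallin, the 6 infected libraries held 2 counts and the treated ones 1382, a ratio of 708 (95% counting interval 196 to 5850). PPP1R3C, a glycogen-targeting phosphatase subunit gene, held 9 and 2095 counts (ratio 239, interval 125 to 522), and CCDC187 2 and 783 counts (ratio 401, interval 111 to 3320). ACTRT3 rose 61.9-fold to 35.9 ± 9.74 CPM (adjusted p = 5.92e-16).

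Of 23 integrated stress response targets, 12 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 7.65e-07, and adjusted p = 0.0316 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, rose from 48.3 ± 3.89 to 269 ± 9.75 CPM (5.57-fold, adjusted p = 2.54e-19). PPP1R15A, whose product directs dephosphorylation of eIF2alpha, rose 4.23-fold to 1613 ± 110 CPM (adjusted p = 3.21e-18) and the amino acid transporter gene SLC3A2 2.33-fold (adjusted p = 2.03e-16). STC2 fell from 4.62 ± 2.34 to 1.03 ± 0.344 CPM (adjusted p = 3.65e-06). HMOX1, the haem oxygenase gene, rose 2.01-fold, from 882 ± 91.8 to 1774 ± 149 CPM (adjusted p = 1.64e-11), and NQO1 1.16-fold (adjusted p = 0.00289). TXNRD1 did not pass (437 ± 24.6 against 453 ± 29.7 CPM, adjusted p = 0.368). Across 32 NRF2 targets, 16 rose and GCLC, SLC7A11, MAFG and ABCC3 fell, also when adjusted over the list alone (camera adjusted p = 0.0557, short of the threshold). Cholesterol biosynthesis genes also rose, with 15 of 23 higher and INSIG1, SREBF2 and LSS lower (16 and 3 when adjusted over the list alone, camera adjusted p = 2.34e-05, and adjusted p = 0.0316 with an estimated correlation). MSMO1 rose 3.2-fold (adjusted p = 5.02e-13) and HMGCS1 2.37-fold (adjusted p = 1.71e-11). INSIG1, which encodes a sterol-regulated inhibitor of SREBP processing, fell from 1431 ± 57.3 to 669 ± 58.4 CPM (adjusted p = 3.62e-13).

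More cytokine and NF-kB target genes fell than rose. Of 12 cytokine genes 7 fell and TNFSF9 and IL18 rose, also when adjusted over the list alone (camera adjusted p = 0.033, but adjusted p = 0.501 with an estimated correlation). TNF fell from 21.4 ± 2.17 to 6.35 ± 1.09 CPM (log2 fold change -1.75, SE 0.099, adjusted p = 1.85e-12), TNFSF15 from 46.2 ± 1.87 to 18.0 ± 2.10 CPM (adjusted p = 5.46e-14) and IL1B from 1520 ± 53.6 to 1167 ± 86.1 CPM (adjusted p = 3.24e-07). TNFSF9, which encodes the ligand of 4-1BB, rose 5.16-fold (adjusted p = 2.11e-15). Of 18 NF-kB targets 11 fell, and TNFAIP3, REL and NFKBIZ rose, also when adjusted over the list alone (camera adjusted p = 0.0223, but adjusted p = 0.542 with an estimated correlation). IER3 fell from 210 ± 32.7 to 44.1 ± 4.93 CPM (log2 fold change -2.25, SE 0.088, adjusted p = 2.11e-15) and BCL3 from 45.9 ± 9.47 to 21.7 ± 2.38 CPM (adjusted p = 1.42e-08). NFKBIZ rose 3.16-fold (adjusted p = 3.84e-10). Of 16 chemokine genes 6 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.0803, short of the threshold), CXCL8 among them (1019 ± 201 against 1496 ± 298 CPM, adjusted p = 0.000402). NLRP3 fell from 111 ± 19.5 to 63.2 ± 3.96 CPM (adjusted p = 2.14e-08) and TXNIP from 235 ± 41.8 to 123 ± 11.7 CPM (adjusted p = 6.97e-09). Log2 fold changes in libraries 1 to 3 and 4 to 6 were -1.06 and -0.54 for NLRP3 and -0.58 and -1.25 for TXNIP. For both genes these differed (adjusted p = 0.000364 and 1.05e-05). Of 42 named genes called with cinnamaldehyde, 41 kept the same sign in both divisions and 19 differed between them. Of 29 immediate-early genes 11 rose and 13 fell, also when adjusted over the list alone (camera adjusted p = 0.489, with a downward direction and median, -0.038, and an upward mean, 0.186). FOS rose 2.08-fold (adjusted p = 5.46e-10). EGR2 fell from 151 ± 20.5 to 32.1 ± 1.65 CPM (adjusted p = 5e-17) and EGR1 from 549 ± 120 to 406 ± 17.3 CPM (adjusted p = 0.000312), the latter not called in libraries 4 to 6 (log2 fold change -0.68 in 1 to 3 and -0.15 in 4 to 6, adjusted p = 0.0875, difference adjusted p = 0.00118). PRDM1, the gene of the repressor BLIMP-1, fell from 164 ± 9.58 to 32.4 ± 4.49 CPM (log2 fold change -2.34, SE 0.071, adjusted p = 1.83e-17). FAT4, TRIM66 and LY6G5B fell with log2 fold changes of -2.27, -2.21 and -2.21 (adjusted p = 5.74e-08, 1.87e-12 and 7.45e-10).

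All 48 ribosomal protein genes rose, also when adjusted over the list alone (median log2 fold change 0.419, camera adjusted p = 1.66e-10, but adjusted p = 0.577 with an estimated correlation), with RPS9 at 1.35-fold, RPL18 at 1.33-fold and RPL19 at 1.33-fold (adjusted p = 2.14e-06, 2.07e-06 and 2.61e-06). Of 31 proteasome genes 29 rose and none fell, also when adjusted over the list alone (median 0.293, camera adjusted p = 8.41e-07, but adjusted p = 0.542 with an estimated correlation). Of 34 nuclear-encoded oxidative phosphorylation genes 29 rose and SDHA fell, also when adjusted over the list alone (median 0.364, camera adjusted p = 2.03e-05, but adjusted p = 0.592 with an estimated correlation). The mitochondrially encoded genes went the other way, with 12 of 13 lower, also when adjusted over the list alone (median -0.716, camera adjusted p = 1.95e-09, but adjusted p = 0.406 with an estimated correlation). MT-CO3 fell from 2290 ± 384 to 1080 ± 71.2 CPM (adjusted p = 1.44e-10), MT-CYB from 1441 ± 213 to 694 ± 48.2 CPM (adjusted p = 4.09e-11) and MT-ND6 from 244 ± 38.7 to 102 ± 13.3 CPM (adjusted p = 1.25e-10). The medians of the 9 lists called kept their sign under DESeq2-type size factors, library totals and TPM. No other list passed, including that of histones (3 rose and 3 fell of 9, camera adjusted p = 0.899) and those of T and NK cell markers (2 of 3 rose, camera adjusted p = 0.597) and fibroblast markers (1 of 3 fell, camera adjusted p = 0.899).

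**Figure D3:**
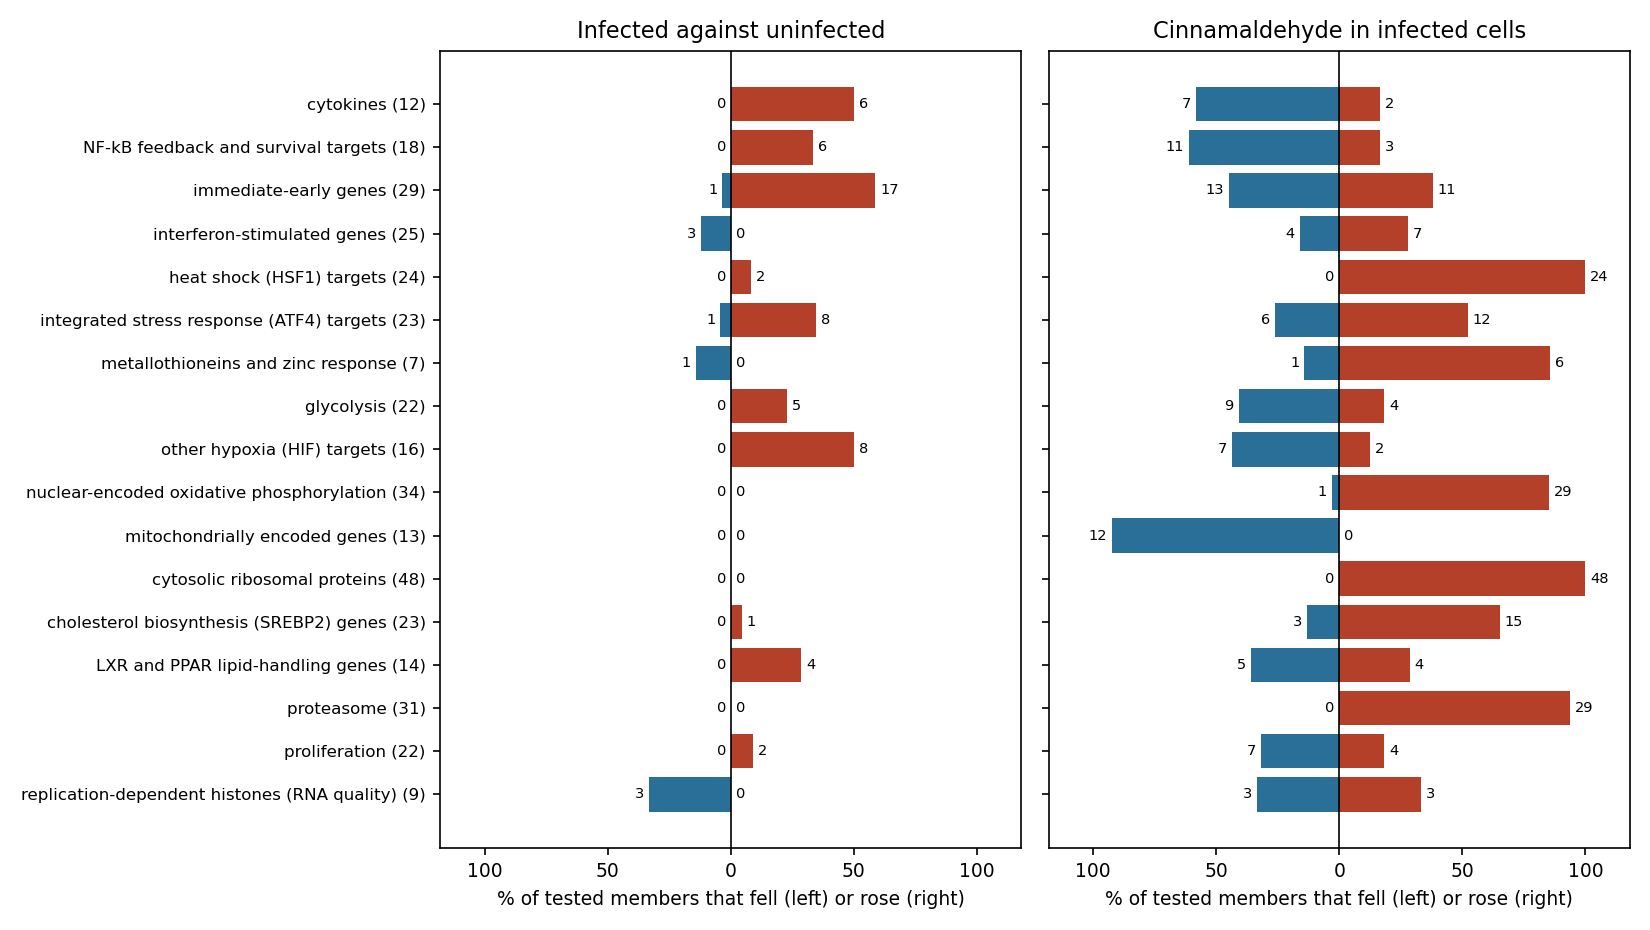
Percent of the tested members of each gene list (members in brackets) that rose (red, right) or fell (blue, left) past edgeR's threshold over all genes, in infected against uninfected cells on the left and in infected cells with against without cinnamaldehyde on the right, for lists called in either comparison. Numbers beside the bars are members, and all 24 heat shock targets and all 48 ribosomal protein genes rose with cinnamaldehyde.

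With cinnamaldehyde 4581 genes were higher and 4816 lower (9397, or 58% of those tested), 349 and 929 of them at least 2-fold. Over all genes tested, the libraries of the 2 groups did not overlap in 5226 (32.3%), against the 0.216% that chance gives. The filter on low counts moved the number of calls of at least 2-fold, which was 2496 without it and 417 with at least 5 CPM in 6 libraries. On log2(TPM + 1) values 469 genes were called at least 2-fold and 32.4% of all calls were higher, against 48.7% in the main test. Within libraries 1 to 3, 9264 genes were called, and within 4 to 6, 7610. The correlation across genes was 0.787, with 2787 genes differing between the divisions and the same direction in 5520 of the 5700 called in both. The heat shock, integrated stress response, cholesterol, ribosomal, proteasome, oxidative phosphorylation, mitochondrial and NF-kB lists were called in both divisions, and the cytokine list in libraries 1 to 3 (camera adjusted p = 0.0017) and not in 4 to 6 (0.128). The glycolysis list (12 of 22 fell, adjusted p = 1.86e-05) and the HIF list (8 of 16 fell and 2 rose, adjusted p = 2.37e-06) were lower in libraries 1 to 3 and did not pass in 4 to 6 (0.996 and 0.888), where 9 glycolysis genes rose and 6 fell and 4 HIF genes rose and 5 fell. In 4 to 6 the chemokine list was lower (8 of 16 fell, adjusted p = 0.00572) and the lysosome list higher (12 of 28 rose and 2 fell, adjusted p = 0.0259), and neither passed in 1 to 3 (0.0847 and 0.549), where 1 chemokine gene rose and 7 fell and 10 lysosome genes rose and 8 fell. With an estimated correlation, the heat shock and cholesterol lists held in both divisions, the cytokine and HIF lists in 1 to 3, and the integrated stress response and mitochondrial lists in 4 to 6. The other 7 calls in 1 to 3 and 6 in 4 to 6 were lost (adjusted p of 0.105 to 0.665 and of 0.337 to 0.665 with an estimated correlation). Whether these lists differed between the divisions was not tested. GAPDH rose 1.09-fold at the edge of the threshold (adjusted p = 0.0498), with a log2 fold change of -0.017 in libraries 1 to 3 and 0.28 in 4 to 6 and of -0.018 on log2(TPM + 1) values. Its call was lost without infected library 2, 3, 4, 5 or 6 or treated library 1, 4 or 5 (adjusted p of 0.0511 to 0.118), and with DESeq2-type size factors or library totals (0.0507 and 0.0962). ACTB fell from 8112 ± 842 to 6573 ± 127 CPM (adjusted p = 2.27e-05). TLR2 (adjusted p = 0.461) and ATF3 (adjusted p = 0.176) did not pass, except ATF3 without treated library 4 (0.021). ATF3 was higher in libraries 1 to 3 (log2 fold change 0.32, adjusted p = 0.000171) and not called in 4 to 6 (-0.07, adjusted p = 0.409), and the divisions differed (adjusted p = 0.0055). TLR2 was called in neither (0.149 and 0.741). On log2(TPM + 1) values the call of NQO1 was lost (adjusted p = 0.0553) and TXNRD1 was lower (-0.20, adjusted p = 7.3e-05). IL6, IL10, CLEC7A and TRPA1 were below the filter on low counts and were not tested. In uninfected, infected and treated libraries IL6 held 0, 0 and 1 counts, IL10 9, 10 and 3, CLEC7A 19, 18 and 18, and TRPA1 44, 38 and 20.

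**Figure D4:**
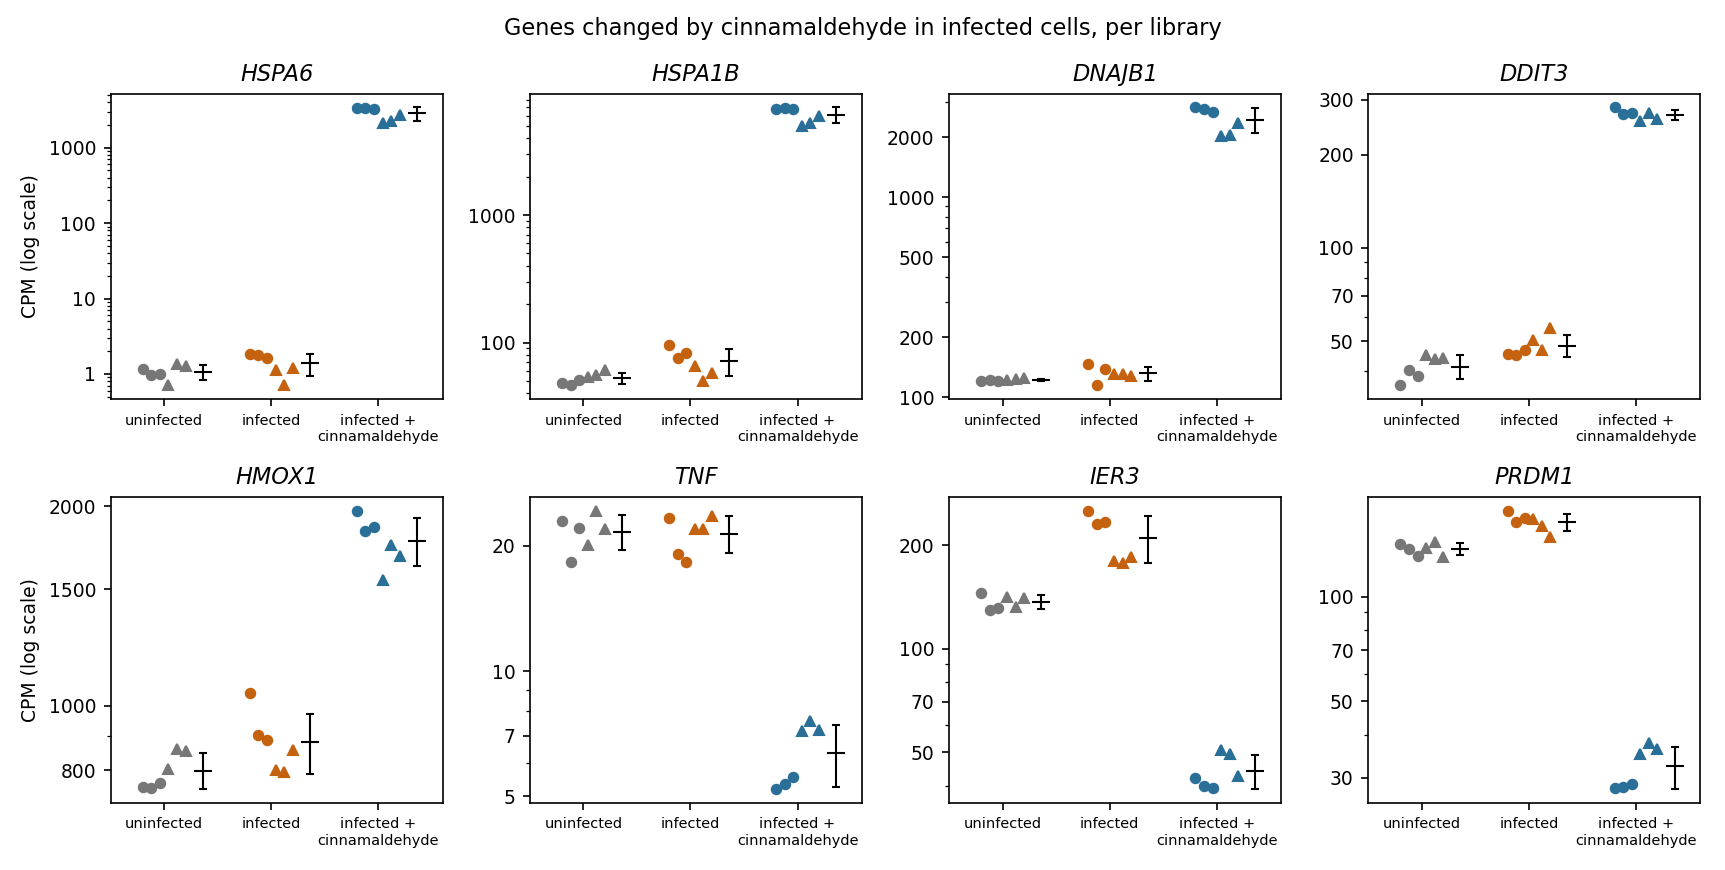
CPM on a log axis of 8 genes that changed with cinnamaldehyde, by group on the x axis. Each point is a library (circles for libraries 1 to 3, triangles for 4 to 6) and the black bar is the mean ± SD over 6 libraries, and TNF lies at 5.21 to 7.59 CPM in the treated libraries and at 18.3 to 24.3 CPM in the others.

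The third comparison, infected cinnamaldehyde-treated against uninfected cells, gave what differed from baseline with both agents present. All 24 heat shock targets were higher than in uninfected cells (camera adjusted p = 6.33e-126, and adjusted p = 6.67e-05 with an estimated correlation). HSPA6 went from 1.08 ± 0.238 to 2837 ± 578 CPM (log2 fold change 11.36, SE 0.19, adjusted p = 2.7e-22), DNAJB1 rose 20-fold (adjusted p = 4.57e-21) and HSPA1A, with the limit on its near-identical copy, 64.1-fold (adjusted p = 2.21e-20). Of the integrated stress response targets 11 rose and CEBPB, SLC7A1 and SLC7A5 fell (camera adjusted p = 3.53e-13, and adjusted p = 0.00202 with an estimated correlation). DDIT3 was 6.5-fold (adjusted p = 4.89e-20), PPP1R15A 5.23-fold (adjusted p = 2.19e-19) and SLC3A2 2.34-fold higher (adjusted p = 2.02e-16), and CEBPB was lower (93.9 ± 7.99 against 140 ± 18.5 CPM, adjusted p = 0.00175). Of the cholesterol genes 17 rose and INSIG1 fell (camera adjusted p = 6.22e-06, and adjusted p = 0.024 with an estimated correlation). MSMO1 was 2.71-fold and HMGCS1 2.16-fold higher (adjusted p = 6.51e-12 and 1.12e-10) and INSIG1 was lower (log2 fold change -0.95, adjusted p = 4.9e-12). All 13 mitochondrially encoded genes fell (camera adjusted p = 2.21e-16, but adjusted p = 0.12 with an estimated correlation), with MT-CO3, MT-CYB and MT-ND6 at log2 fold changes of -1.27, -1.23 and -1.54 (adjusted p = 1.08e-11, 3.21e-12 and 3.95e-12). For these 4 lists the counts were the same when adjusted over the list alone.

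All 48 ribosomal protein genes, 28 of 31 proteasome genes and 30 of 34 oxidative phosphorylation genes rose and none of them fell (camera adjusted p = 4.87e-08, 6.22e-06 and 0.000744, but adjusted p = 0.656, 0.571 and 0.715 with an estimated correlation). Of the NRF2 targets 18 rose and 4 fell (20 and 5 when adjusted over the list alone, camera adjusted p = 0.0188, but adjusted p = 0.525 with an estimated correlation). Of 28 lysosome genes 12 rose and NPC1 fell (camera adjusted p = 0.0203, but adjusted p = 0.525 with an estimated correlation), and the median of this list turned from 0.098 to -0.010 on log2(TPM + 1) values. Of the immediate-early genes 16 rose and 10 fell (camera adjusted p = 0.0312, but adjusted p = 0.698 with an estimated correlation). Apart from the NRF2 list, these counts were the same when adjusted over the list alone. CYP1B1, a cytochrome P450 gene, fell from 394 ± 34.5 to 92.4 ± 3.69 CPM (log2 fold change -2.09, adjusted p = 7.96e-17) and PRDM1 from 137 ± 5.68 to 32.4 ± 4.49 CPM (adjusted p = 1.88e-16). TRIM66 and LY6G5B fell with log2 fold changes of -2.23 and -2.16 (adjusted p = 1.62e-12 and 1.24e-09). The uninfected libraries held 3 counts of CRYAB, 9 of PPP1R3C and 1 of CCDC187, for ratios of 466 (95% counting interval 159 to 2260), 236 (124 to 516) and 793 (142 to 31300). In all, 4026 genes were higher and 4176 lower (8202), 338 and 847 of them at least 2-fold. Over all genes tested, the groups did not overlap in 5272 (32.6%), against the 0.216% that chance gives. Within libraries 1 to 3 and 4 to 6, 6209 and 7891 genes were called, with a correlation of 0.833 across genes and 31 genes differing between the divisions. The NRF2 list passed in neither division (camera adjusted p = 0.0577 and 0.0838), and the other 9 lists given for this comparison passed in both. The chemokine list, which did not pass over all libraries (camera adjusted p = 0.0615), was lower in both (6 and 9 of 16 fell, adjusted p = 0.00147 and 0.039, but adjusted p = 0.379 and 0.62 with an estimated correlation). The unfolded protein response list was higher in libraries 4 to 6 (adjusted p = 0.039, but adjusted p = 0.348 with an estimated correlation) and did not pass in 1 to 3 (0.34), a difference that was not tested. With an estimated correlation, the heat shock, integrated stress response, cholesterol and mitochondrial lists held in both divisions, and the calls of the others were lost (adjusted p of 0.188 to 0.814). The calls of at least 2-fold numbered 2313 without the filter and 347 with at least 5 CPM in 6 libraries. With library totals 38.2% of calls were higher, against 49.1%.

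The last comparison asked how far the changes seen with infection were moved back or further by cinnamaldehyde. Of the 33 genes that changed at least 2-fold with infection, 23 were called in the opposite direction with cinnamaldehyde, 15 of them higher and 8 lower in infected cells, and 6 in the same direction. DDIT4 (log2 fold change 2.22 with infection and -1.64 with cinnamaldehyde), CXCR4 (1.42 and -1.21), PNRC1 (1.35 and -0.51), STC2 (1.39 and -2.14), HILPDA (1.22 and -1.31) and ANGPTL4 (1.84 and -2.17) were among those moved back. The ID3 and ID1 genes, inhibitors of basic helix-loop-helix factors, were lower with infection (-2.68 and -1.21) and higher with cinnamaldehyde (3.92 and 0.90). NR4A1 (3.06 and 2.58) and FOSB (1.31 and 1.89) were higher with both. HILPDA, ANGPTL4, ID3, ID1 and NR4A1 were named after their values had been seen, and the group means of ID3 were 1.44, 0.22 and 3.41 CPM in uninfected, infected and treated cells. ADM, NR4A2 and ANKRD37 were not called with cinnamaldehyde (adjusted p = 0.351, 0.262 and 0.978).

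The changes with cinnamaldehyde were uneven between the divisions for part of these genes. Of the 23 genes moved back, 20 were called in the opposite direction to infection in libraries 1 to 3 and 15 in 4 to 6. Of them 13 were so called in both, and 9 differed between the divisions. The direction of infection was taken here from all libraries, so these genes need not have changed with infection within 4 to 6. Within 4 to 6 alone, 5 genes changed at least 2-fold with infection. Of those, 2 were called in the opposite and 1 in the same direction with cinnamaldehyde. ADM fell in libraries 1 to 3 (log2 fold change -1.10, adjusted p = 3.06e-11) and rose in 4 to 6 (0.99, adjusted p = 7.44e-10), and the divisions differed (adjusted p = 2.64e-11). PNRC1 fell in 1 to 3 (-1.02, adjusted p = 1.03e-11) and was not called in 4 to 6 (0.13, adjusted p = 0.0997), with a difference between them (adjusted p = 6.31e-08). For ANGPTL4 the values were -3.18 and -0.15, for HILPDA -1.79 and -0.31, for DDIT4 -2.30 and -0.25, for CXCR4 -1.85 and -0.41 and for STC2 -3.19 and -0.91, and each differed (adjusted p = 0.000842 or less). HILPDA and ANGPTL4 were not called in 4 to 6 (adjusted p = 0.201 and 0.53). For ID3 (3.93 and 3.90) and ID1 (0.93 and 0.86) a difference was not detected (adjusted p = 0.979 and 0.888). NR4A2 was lower in 1 to 3 (-0.43, adjusted p = 0.0324) and not called in 4 to 6 (-0.09, adjusted p = 0.728), and its difference did not pass (adjusted p = 0.372). ANKRD37 was called in neither (adjusted p = 0.54 and 0.349).

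Both comparisons contain the infected libraries, with opposite signs, so opposite changes arise from their spread alone. Over 20 simulations with no effect, the 33 genes of smallest p with infection had opposite signs in 95.8% of cases (87.9% to 100%), against 78.8% of the 33 of smallest p observed. These simulations rarely called a gene (2 at most, in 1 simulation), so their 33 genes were mostly noise, whereas the observed 33 were all called. The 2 percentages are therefore not comparable and do not show less or more moving back than chance gives. The simulated correlation given below has the same limit. Independent lists of the same sizes would share 6.25 and 3.4 genes in opposite directions (higher and lower with infection) and 5.94 and 3.57 in the same direction. The correlation of the log2 fold changes across genes was -0.278, against -0.499 simulated, and the covariance -0.0442 against -0.0144, a difference of -0.0299. Over the 20 ordered splits of 3 and 3, each comparison had different infected libraries. A mean of 38 genes were called at least 2-fold with infection. Of these a mean of 14.9 (4 to 44) were called in the opposite and 6.55 (0 to 44) in the same direction. The mean correlation was -0.16 and the mean covariance -0.0304. Both maxima of 44 came from the split with infected libraries 1 to 3 for infection and 4 to 6 for cinnamaldehyde. That split called the most genes at least 2-fold with infection (169) and had no excess of opposite calls among them. At any fold, it gave 2231 opposite and 1080 same-direction calls out of 6165. The 23 opposite calls became 12, 15, 14 and 36 without infected library 1, 2, 3 or 5, and the 6 same-direction calls 3, 3, 3 and 10.

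The lead genes lie on the GRCh38 build as follows, over their whole annotated span. DDIT4 (ENSG00000168209) spans 72273920 to 72276036 of chromosome 10, ADM (ENSG00000148926) 10304680 to 10307397 of chromosome 11, CXCR4 (ENSG00000121966) 136114349 to 136118165 of chromosome 2, and SLC30A1 (ENSG00000170385) 211571568 to 211578742 of chromosome 1. HSPA6 (ENSG00000173110) spans 161524540 to 161526910 of chromosome 1, DNAJB1 (ENSG00000132002) 14514770 to 14529770 of chromosome 19, HSPA1A (ENSG00000204389) 31815464 to 31817946 and HSPA1B (ENSG00000204388) 31827735 to 31830255 of chromosome 6. DDIT3 (ENSG00000175197) spans 57516588 to 57521737 of chromosome 12, TNF (ENSG00000232810) 31575567 to 31578336 of chromosome 6, IER3 (ENSG00000137331) 30743199 to 30744554 of chromosome 6, and PRDM1 (ENSG00000057657) 106086320 to 106109939 of chromosome 6. Counts were given per gene, so exons, introns and untranslated regions are not distinguished in these values.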

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

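The tests on libraries 1 to 3 against 4 to 6 and on the chaperone share, and the division of lncRNA genes by a known location or overlap, were chosen after the results they concern had been seen, and the other tests before. A test of a batch shared by library number, and of labels exchanged between infected and uninfected libraries (highest uninfected library 0.2858 on the second component, infected median 7.02), were run first and replaced or dropped after their results had been seen. Of 240 groups of 6 libraries examined for a library far from the rest, 7 held such a library, against the 12 that chance gives at 5%. CCDC187 was at 0.0473 CPM in uninfected library 4 and at 0.0942 CPM in infected library 5, with 0 in the other libraries of each group. On the first component infected library 5 lay at -16.54, with the next at -18.53. PIK3R2 was at 25.3 CPM in infected library 1, with the next highest at 14.03. Among treated libraries, CEBPB was at 110.0 CPM in library 5 (next 92.2), LIF at 5.27 CPM in library 1 (next 6.48) and TNFAIP3 at 77.5 CPM in library 6 (next 66.3).

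The infected libraries spread over 26 units of the second component. Sequencing depth was argued against: thinned to the smallest total, they still spread over 25.5 units, against 12.8 for the uninfected libraries. A shift of libraries 1 to 3 against 4 to 6 in the same genes and the same direction in every group was argued against. Over the 3782 genes that differed between these infected libraries, the difference had a correlation of 0.0435 with that in treated libraries. With the difference in uninfected libraries the correlation was -0.337 (0.186 between treated and uninfected). Shifts in opposite directions are not covered by this test. A difference tied to library number outside infection thus stays open. Separate handling of the libraries with an unequal degree of infection may account for the spread and stays open: 88 genes differed between uninfected libraries 1 to 3 and 4 to 6 (1 at most in the 9 other splits), but in the treated group 48 did and another split gave 961. A biological difference between cultures stays open as well, as untested.

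Ribosomal protein, proteasome and respiratory chain genes were higher with cinnamaldehyde. Lists matched on transcript length, GC content and expression were drawn for comparison. The median of the ribosomal protein genes was 0.238 higher (0.419 against 0.181, 95% of matched lists 0.107 to 0.263). That of oxidative phosphorylation genes was 0.125 higher (0.364 against 0.24, 0.157 to 0.312). Matched genes were drawn singly, whereas members of these 2 lists moved together (estimated correlation 0.86 and 0.553). The ranges are thus too narrow for such lists and cannot decide whether length and GC content were the whole cause. For the proteasome the excess was 0.0787 (0.293 against 0.215, 0.126 to 0.302), so length and GC content may account for that rise. As arithmetic and not an independent test, the larger share of 7 chaperone genes, already seen, shifts all other genes by -0.0271 and so cannot raise them. An effect of cinnamaldehyde on these lists stays a hypothesis.

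Genes that are not protein-coding fell more often with cinnamaldehyde: 16.2% of 3471 were lower by at least 2-fold, against 2.88% of 12718 protein-coding genes, and 4.32% against 1.56% were higher by at least 2-fold. Low counts were argued against as the whole cause, since protein-coding sets matched on CPM gave 6.77% (95% of sets 5.96 to 7.58). That was above the 2.88% of all protein-coding genes, so a part played by low counts stays open. Unspliced RNA of overlapping protein-coding genes was argued against as the whole cause for the 1760 lncRNA genes with a known location, since 17.7% of the 750 without such overlap fell, against 6.86% in matched sets (5.2 to 8.67). Of 170 with a protein-coding gene on the same strand 37 fell (21.8%, Fisher's exact test against those without overlap p = 0.229), so a part played by overlap stays open. For the other 997 lncRNA genes, of which 17% fell, overlap is unknown, so there this explanation and an effect of cinnamaldehyde cannot be told apart.

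Of 100 of the 462 splits of the 12 libraries compared, the labelled split alone reached its gene count. The other splits mix the groups, so a group difference widens the spread within each set and makes calls unlikely there. Chance differences between cultures are not excluded by these splits, since the labels do not say that libraries came from separate cultures. With only those groups in the fit, infection gave 206 genes (1 of 100 splits as large, highest other 1), cinnamaldehyde 8967 (1 split, highest other 0) and the third comparison 8925 (1 split, highest other 0). For the 22 genes moved back by cinnamaldehyde the count decides nothing (1 split, highest other 0), since the other splits called no gene and could move none back. For infection, 14 lists were called, a number that 2 of 100 splits reached, the labelled one among them (highest other 14). So large a number was rare, but a wrong grouping equalled it, so chance was not excluded for any single list. Chance was not excluded for the number of lists with cinnamaldehyde (8, with 30 of 100 splits as large, highest other 12). The same held in the third comparison (9, with 31, highest other 15).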

How the results depend on the processing

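The direction of some named genes and of 1 library measure changed with the setting, and the cause was not tested. The log2 fold change of CXCL8 with infection became -0.005268 with library totals, and -0.007272, -0.006134, -0.02245, -0.056 and -0.008021 without uninfected library 3 or 6 or infected library 4, 5 or 6. TNF with infection became 0.0174 on log2(TPM + 1), and 0.001946, 0.0332, 0.01416 and 0.02399 without uninfected library 1 or 5 or infected library 2 or 3. GAPDH, TLR2 and ATF3 with cinnamaldehyde became -0.01777, -0.04572 and -0.03713 on log2(TPM + 1). The share of the 10 most abundant genes differed by -0.08167, -1.239 and -1.32 percentage points in shares of TPM.

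The infection count of 772 depended most on the setting. It was 1302 without the filter (40146 genes tested), 1560 with DESeq2, 438 with limma-voom, 206 with only the 2 groups in the fit, 167 and 155 on log2(TPM + 1) and log2(TPM + 0.1), 73 on log2(TPM + 1) without a filter and 8 against a 1.5-fold change. The 33 genes of at least 2-fold became 99 without the filter, 10 with at least 5 CPM in 6 libraries, 17 with DESeq2, 10 and 13 on the TPM scales, 4 on TPM without a filter and 18 among protein-coding genes. Leaving out a library gave 197 to 2676 genes, and 18 to 57 of at least 2-fold. Over the 20 choices of 3 infected libraries, added after the data had been seen, 69 to 5932 genes were called, and 6 to 163 of at least 2-fold. Within libraries 1 to 3 and 4 to 6, also added, 6710 and 68 were called, and 229 and 5 of at least 2-fold. The cause was not tested beyond fewer libraries or genes entering a test.

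The 9397 genes with cinnamaldehyde were 8855 to 9628 and the 8202 of the third comparison 7654 to 8123 when a library was left out, and 1398 and 1225 against a 1.5-fold change. At least 2-fold, 1278 and 1185 became 2496 and 2313 without the filter, 417 and 347 with the stricter filter, 469 and 376 on log2(TPM + 1), 507 and 407 on TPM without a filter and 584 and 506 among protein-coding genes, and 1208 to 1341 and 1122 to 1243 when a library was left out. On log2(TPM + 0.1) the median of all genes shifted by -0.129 and -0.102. Lists called fell to 3, 3 and 3 with an estimated correlation, and fry called 26 with cinnamaldehyde and 22 in the third comparison. The first component held 52.6% of variance with 5000 genes and 63% on log2(TPM + 1). The 23 genes moved back and 6 moved further became 519 and 82 of 772 at any fold, 11 and 3 with DESeq2, 14.9 back on average with split infected libraries, 141 and 16 of 229 within libraries 1 to 3, 2 and 1 of 5 within 4 to 6 (added after the data had been seen), and 12 to 36 and 3 to 10 when a library was left out.

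With the library number as a block, 246 genes were called with infection (20 at least 2-fold), 9138 with cinnamaldehyde and 7955 in the third comparison, and 13 genes were moved back. The calls of CEBPG, ACTB, EGR1, DDIT3 and PIK3R2 with infection were lost (adjusted p = 0.0996, 0.0975, 0.0504, 0.0797 and 0.0797), as were those of GAPDH (0.0681) and the NF-kB list (0.0561) with cinnamaldehyde. The numbers did not meet the rule used for pairing, which asked that all 6 same-numbered pairs correlate over 0.1. Same-numbered libraries correlated at -0.601 to 0.212, -0.398 to 0.305 and -0.0355 to 0.495 in the 3 comparisons. Of 6 pairs 2, 2 and 4 were over 0.1, and 0, 1 and 2 of 6 correlated best with their own number. In the third comparison libraries 1, 3, 5 and 6 gave 0.362, 0.215, 0.409 and 0.495. Their means with other numbers were -0.0559, -0.0244, -0.106 and -0.124. Libraries 2 and 4 gave 0.00868 and -0.0355. Variation shared by number in part of the libraries thus stays open. Low counts kept IL6, IL10, CLEC7A and TRPA1 out of the tests, so no statement is made on changes in them. Among named genes, calls lost with the direction kept numbered 3 with limma-voom, 11 on log2(TPM + 1), 3 with library totals, 1 with DESeq2-type size factors and 0 with DESeq2. On log2(TPM + 1) the call of GAPDH with cinnamaldehyde was lost as well, with its direction turned (limma adjusted p = 0.824). Calls gained numbered 1 with DESeq2 and 1 on log2(TPM + 1).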

Other observations

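The genes named here were chosen after their values had been seen, and the tests of both hypotheses were fixed before. With cinnamaldehyde the immediate-early list split. DUSP2, which encodes a MAP kinase phosphatase, rose with a log2 fold change of 4.76 (edgeR adjusted p = 9.69e-21), CCN1 with 3.16 (adjusted p = 1.93e-11), KLF2 with 1.45 (adjusted p = 6.51e-08) and JUN with 1.21 (adjusted p = 3.17e-09). BTG2, DUSP6 and JUNB fell with -2.10, -1.40 and -1.17 (adjusted p = 1.19e-17, 8.95e-16 and 6.64e-10). Of 21 apoptosis regulators 9 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.783). The BH3-only genes PMAIP1 (0.96) and BIK (0.57) rose, and BMF (-1.13), BCL2L11 (-0.96) and BBC3 (-0.96) fell. Of 12 inflammasome and pyroptosis genes 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.297), with CASP1 higher by 1.44 (adjusted p = 2.94e-15) and NLRP3 lower.

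Among genes that are not protein-coding, MIR124-1HG fell from 17.8 ± 2.47 to 1.27 ± 0.391 CPM with cinnamaldehyde (log2 fold change -3.80, adjusted p = 4.42e-15) and MIR142HG from 8.52 ± 1.44 to 0.909 ± 0.0848 CPM (adjusted p = 1.41e-13). CD2BP2-DT rose from 3.16 ± 0.500 to 37.8 ± 6.45 CPM (adjusted p = 2.03e-16). TM4SF19-AS1 was higher with infection (0.89, adjusted p = 0.00946) and lower with cinnamaldehyde (-2.09, adjusted p = 1.77e-08). The near-identical signal recognition particle RNA genes RN7SL1 and RN7SL2 were lower with infection (-1.07 and -1.09, adjusted p = 0.0107 and 0.00654). RN7SL1 went from 70.86 ± 13.43 to 33.78 ± 14.02 CPM and RN7SL2 from 115.7 ± 29.36 to 54.4 ± 18.54 CPM. Both count among the 12 falls of at least 2-fold and the 23 genes moved back. The histone list, fixed as a sign of RNA quality, fell with infection too (camera adjusted p = 0.00016, but adjusted p = 0.12 with an estimated correlation). Whether unequal RNA quality or polyA selection lowered both genes was not tested. Reads of antisense genes are uncertain because use of strand in the counting is not given in the sources used here.

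A first hypothesis was that transcription ran past gene ends in these cells, as is known of heat shock, and would raise genes just downstream of expressed genes. The result went the other way for 174 non-coding genes within 5 kb downstream on the same strand. Their median log2 fold change was -0.46, against -0.198 in matched sets (95% of sets -0.309 to -0.0868). For 1016 protein-coding genes so placed it was -0.0999, against 0.0241 (-0.00447 to 0.0521). Only polyA RNA was counted, per annotated gene and with use of strand not given. RNA past gene ends was thus not measured directly, and these values do not exclude it. A second hypothesis was that splicing was reduced, which would raise genes without introns. The median of 470 single-exon protein-coding genes was -0.211, against 0.0574 in matched sets (0.0162 to 0.0991), also opposite to the prediction. Counts per gene do not tell exons from introns, so splicing was not measured directly and these values do not exclude its reduction.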
